A study of Homo sapiens with 14 samples.

How the data were processed

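Affymetrix 3-prime expression arrays were read for 14 samples of PANC-1 cells. Per the labels, cells grown in 10% serum were kept for 24 h in 1% serum and then treated for 48 h, and 200 ng of RNA was labelled as biotin cRNA. The groups were control (4 arrays), TGFb1 at 5 ng/ml (4), TGFb1 with acriflavine at 2.5 µM (3) and TGFb1 with sodium valproate at 2 mM (3). The labels call the replicates biological, and replicate 4 of the control and of the TGFb1 group was profiled in addition to the other 3. An acriflavine group without TGFb1 was not analysed here.

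The deposited values are log2 intensities that the authors made by RMA (background correction, quantile normalisation between arrays and median polish) with the R package affy 1.44.0. Which arrays were normalised together is not stated. The table held 49193 probe sets with values from 2.97 to 15.1 and 0 missing values. Of these, 44898 named 1 gene, 1825 named several and 2470 were unnamed here. Symbols were checked by gene identifier against a RefSeq table, which matched 44871 probe sets and changed 0 symbols. Genome positions were not used here.

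For each of 18129 genes, 11714 of which had more than 1 probe set, the probe set with the highest mean over all arrays was kept. The dimmest 40% of genes by mean over all arrays, 7252 genes, were left out, so that 10877 genes with means of at least 6.88 were tested. Linear models with 1 mean per group were fitted over all 14 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 6 comparisons were tested with Benjamini-Hochberg adjustment over genes at an adjusted p of 0.05. The SE is that of this fit. Of 35 gene lists with 976 entries and 913 genes, 660 genes were tested, and lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01. The adjustment was over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list moves one way without setting it against other genes, were run beside it. 4 lists held markers of other cell types.

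Named genes followed a rule: the 10 largest rises and 10 largest falls for TGFb1 against control and for each inhibitor against TGFb1, among genes that passed and whose arrays did not overlap between groups. The rule took 5 and 5 for acriflavine against valproate and 3 and 3 for the comparisons with control. It added from each list up to 3 members that passed and 1 that did not, and a short list of marker genes whatever their result. SNAI2, ZEB2, TWIST1 and ESRP1, which are known regulators of epithelial-mesenchymal transition, lay below the brightness limit and have no test. Their group means in control, TGFb1, acriflavine and valproate arrays were 5.18, 7.03, 7.15 and 7.94 for SNAI2 and 7.50, 6.43, 5.42 and 7.45 for ESRP1, and all of those of ZEB2 and TWIST1 lay between 3.84 and 5.23.

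The replicate number was taken as a pair where, in every replicate, the deviations from the group means correlated across genes above 0.1 between both groups. For control and TGFb1 they did (0.387, 0.359, 0.543 and 0.705), though with replicates 1 to 3 alone the values were -0.258, 0.151 and 0.589. The other comparisons were not paired by this rule. Alternatives were other brightness limits, each probe set separately, the mean of probe sets, probe sets ending in _x_at left out, other scalings between arrays, another variance model, fits of 2 groups alone, the replicate block, a stricter adjusted p of 0.01, a minimum fold of 2 and each array left out in turn. The replicates 4 were also left out together. A batch term for the replicates 4, and leaving out TGFb1 replicate 2 with them, were added after the data were seen. The comparisons, gene lists, naming rule and other alternatives were chosen before the data were examined.

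On data simulated with the measured spread, 1 simulation per comparison, the fit found 36.2% to 57.8% of genes with a true log2 change of 0.5 and 87.0% to 95.5% of those with a change of 1. Between 2.92% and 8.20% of its calls were false. A list of 29 genes shifted by -0.5 was called and 0 other lists were. The simulated genes were independent of each other, so the list result does not cover false calls where genes of a list are correlated. The number of arrays limits the precision. A planned comparison of RNA quality by control probe sets for the ends of long transcripts was not run, because 0 probe sets of that kind were in the table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.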

Results

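The data describe PANC-1, an established human pancreatic carcinoma cell line, after 48 h with TGFb1, a cytokine known to drive the loss of epithelial and gain of mesenchymal traits (epithelial-mesenchymal transition). Expression arrays were read for 14 samples: 4 control samples, 4 samples with TGFb1 alone at 5 ng/ml, 3 with TGFb1 and acriflavine at 2.5 µM, and 3 with TGFb1 and sodium valproate at 2 mM. Acriflavine is a mixture of acridine dyes that binds nucleic acids, and valproate is an inhibitor of histone deacetylases. Values are log2 intensities, and changes are differences of group means on the log2 scale ± standard error (SE) of the limma fit. A gene rose or fell where its adjusted p passed 0.05 among the 10877 genes tested. The number of arrays limits the precision.

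The array medians lay between 7.16 and 7.21 log2 units. Principal component 1 held 41.4% of the variance and parted the 3 acriflavine arrays from the rest, and component 2 held 23.2% and parted the 4 control arrays from the valproate arrays, with the TGFb1 arrays between. Replicate 4 of the control group and replicate 4 of the TGFb1 group stood apart from their groups. The standard deviation (SD) of an array's deviation from its group mean was 0.375 for TGFb1 replicate 4, 0.256 for TGFb1 replicate 2 and 0.250 for control replicate 4, against 0.0665 to 0.160 for the other 11 arrays.

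**Figure D1:**
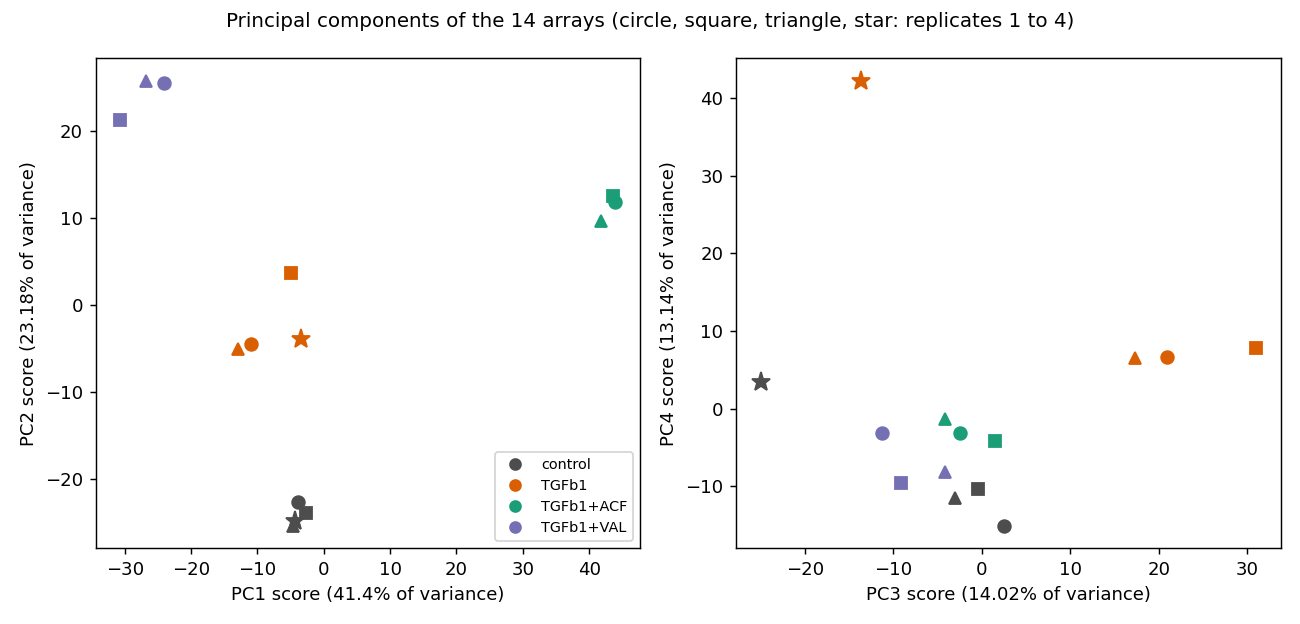
Principal component scores of the 14 arrays over the 10877 genes tested, with component 1 against component 2 and component 3 against component 4, marked by group and replicate. Component 4, with 13.1% of the variance, set TGFb1 replicate 4 apart at 42.2 from all other arrays, which lay between -15.1 and 7.81.

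TGFb1 alone was compared with control to show the response on which the inhibitors act. CDH1, the adhesion protein E-cadherin of epithelial junctions, fell from 8.98 ± 0.688 (SD, n = 4) to 6.58 ± 0.252 (SD, n = 4), a change of -2.40 ± 0.259 (adjusted p = 2.08e-05). SNAI1, a transcription factor that represses CDH1, rose by 2.63 ± 0.146 (adjusted p = 3.57e-08), and COL1A1, a chain of type I collagen, rose by 3.68 ± 0.254. 20 of 34 epithelial genes and 20 of 29 interferon-stimulated genes fell, and 18 of 24 genes of TGFb signalling and 15 of 31 mesenchymal genes rose. In all, 913 genes rose and 1084 fell, and 136 of the former and 144 of the latter changed at least 2-fold.

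The largest rises were in ADAM19 (3.91 ± 0.211), a membrane-bound metalloprotease, COL1A1, NKAIN4 (3.52 ± 0.192), TUBA4A (3.16 ± 0.0935), an alpha-tubulin, SPOCK1 (3.06 ± 0.315), a matrix proteoglycan, and ANGPTL4 (3.01 ± 0.127), an inhibitor of lipoprotein lipase. P4HA3, a subunit of the enzyme that hydroxylates collagen prolines, rose by 2.77 ± 0.144, and COL5A1, a chain of type V collagen, by 2.69 ± 0.117. The largest falls were in INHBB (-2.85 ± 0.0978), the beta B subunit of activin and inhibin, LCN2 (-2.85 ± 0.202), a secreted siderophore-binding protein, CDH1, PPP1R1B (-2.33 ± 0.151) and the interferon-induced IFIT2 (-2.31 ± 0.146). By the rule that chose these genes, every TGFb1 array lay on the same side of every control array for each of them.

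Of 34 measured epithelial genes, 20 fell, 1 rose and 13 did not pass (adjusted p = 6.77e-08 by camera, adjusted p = 0.165 with an estimated correlation; adjusted over the list alone, 1 rose and 21 fell). ELF3, an epithelial transcription factor, was at -1.96, CLDN3, a tight junction claudin, at -1.40, and EPCAM, an epithelial adhesion protein, at -1.38. Of 31 mesenchymal genes 15 rose, 1 fell and 15 did not pass (adjusted p = 9.19e-08, and adjusted p = 0.00168 with an estimated correlation; adjusted over the list alone, 19 rose and 1 fell). CDH2, N-cadherin, rose by 0.48. VIM, the intermediate filament vimentin, was at 0.15 and did not pass (adjusted p = 0.0933), nor did FN1, fibronectin, at 0.76 (adjusted p = 0.0964; adjusted p = 0.00148 with the replicate number as a block, 0.97 with adjusted p = 0.0439 without TGFb1 2, and 0.39 with adjusted p = 0.116 without TGFb1 4). 18 of 24 genes of TGFb-SMAD feedback rose and none fell (adjusted p = 5.7e-14, and adjusted p = 0.000369 with an estimated correlation; adjusted over the list alone, 19 rose and 0 fell), among them PMEPA1 (1.89) and SMAD7 (1.31), which dampen the pathway, and NOG (2.47), a secreted BMP antagonist.

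Of 22 genes of collagens and basement membrane, 9 rose and 6 fell (adjusted p = 0.0448 by camera, adjusted p = 0.165 with an estimated correlation; adjusted over the list alone, 9 rose and 6 fell), with COL4A1, a basement membrane collagen, up by 2.56. Of 26 genes of integrins and the actin cytoskeleton, 11 rose and 3 fell (adjusted p = 0.000426 by camera, adjusted p = 0.165 with an estimated correlation; adjusted over the list alone, 12 rose and 3 fell). ITGA5, a chain of the fibronectin receptor, rose by 1.64 and MYO10, a motor of filopodia, by 1.56. 6 of 15 matrix proteases and inhibitors rose and 3 fell (adjusted p = 0.0176 by camera, adjusted p = 0.165 with an estimated correlation; adjusted over the list alone, 8 rose and 3 fell), with gelatinase MMP2 up by 1.25 and its inhibitor TIMP2 by 1.27. In the list of fibroblast and stellate cell genes, which shares COL1A1, COL3A1 and others with the lists above, 3 of 5 rose (adjusted p = 0.00557 by camera, adjusted p = 0.142 with an estimated correlation; adjusted over the list alone, 3 rose and 0 fell). Hepatocyte, leukocyte and endothelial lists each had 3 measured genes and were not tested as lists. Of their members, RBP4 fell by 1.11, LAPTM5 rose by 0.87 and ESAM by 1.73.

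Interferon-stimulated genes fell in 20 of 29 and rose in none (adjusted p = 5.7e-14 by camera, adjusted p = 0.165 with an estimated correlation; adjusted over the list alone, 0 rose and 21 fell). IFIT2 was at -2.31 and MX1, an antiviral GTPase, at -2.19. Of 20 NF-kB cytokine and inflammation genes 6 fell and 1 rose (adjusted p = 0.00277 by camera, adjusted p = 0.302 with an estimated correlation; adjusted over the list alone, 1 rose and 8 fell). The chemokines CCL20 (-2.28), CXCL5 (-2.16) and CCL5 (-1.77) fell, and the cytokine IL11 rose by 2.23. Among 39 proliferation genes 11 rose and none fell (adjusted p = 0.000122 by camera, adjusted p = 0.484 with an estimated correlation; adjusted over the list alone, 11 rose and 0 fell), with FOXM1, a transcription factor of the G2/M genes, at 0.52 and the marker MKI67 at 0.30 (adjusted p = 0.46; -0.02 without TGFb1 replicate 4).

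Replicate numbers paired the TGFb1 and control arrays by the rule used, but the arrays of replicates 1 and 2 were not each other's closest match. With replicates 1 to 3 alone the deviations correlated at -0.258, 0.151 and 0.589, so true pairs are not established. With the number as a block 3148 genes changed, including all 1997. Within replicates 1 to 3 and within the pair of replicates 4, the mean TGFb1 minus control difference was -0.471 and -0.910 for the epithelial list, 0.858 and 0.803 for the TGFb-SMAD list and 0.537 and 0.433 for the mesenchymal list. It was -0.834 and -1.37 for the interferon list, -0.274 and -1.02 for NF-kB and 0.124 and 0.654 for proliferation. For the 33 genes of ATF4 and the amino acid response it was -0.00395 and -0.733, and this list passed with the block (adjusted p = 0.0469) but not without it (adjusted p = 0.0746). It also passed without control 4 (0.0335) and without TGFb1 1, 2 or 3 (0.0119, 0.0313 and 0.0112). Without the replicates 4, 3155 genes changed, of which 1870 were among the 1997. The proliferation and NF-kB lists did not pass without TGFb1 replicate 4 (means 0.11 and -0.38, adjusted p = 0.0574 for each), and the collagen list did not without control 1 (0.0622), TGFb1 3 (0.0722) or TGFb1 4 (0.0819).

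**Figure D2:**
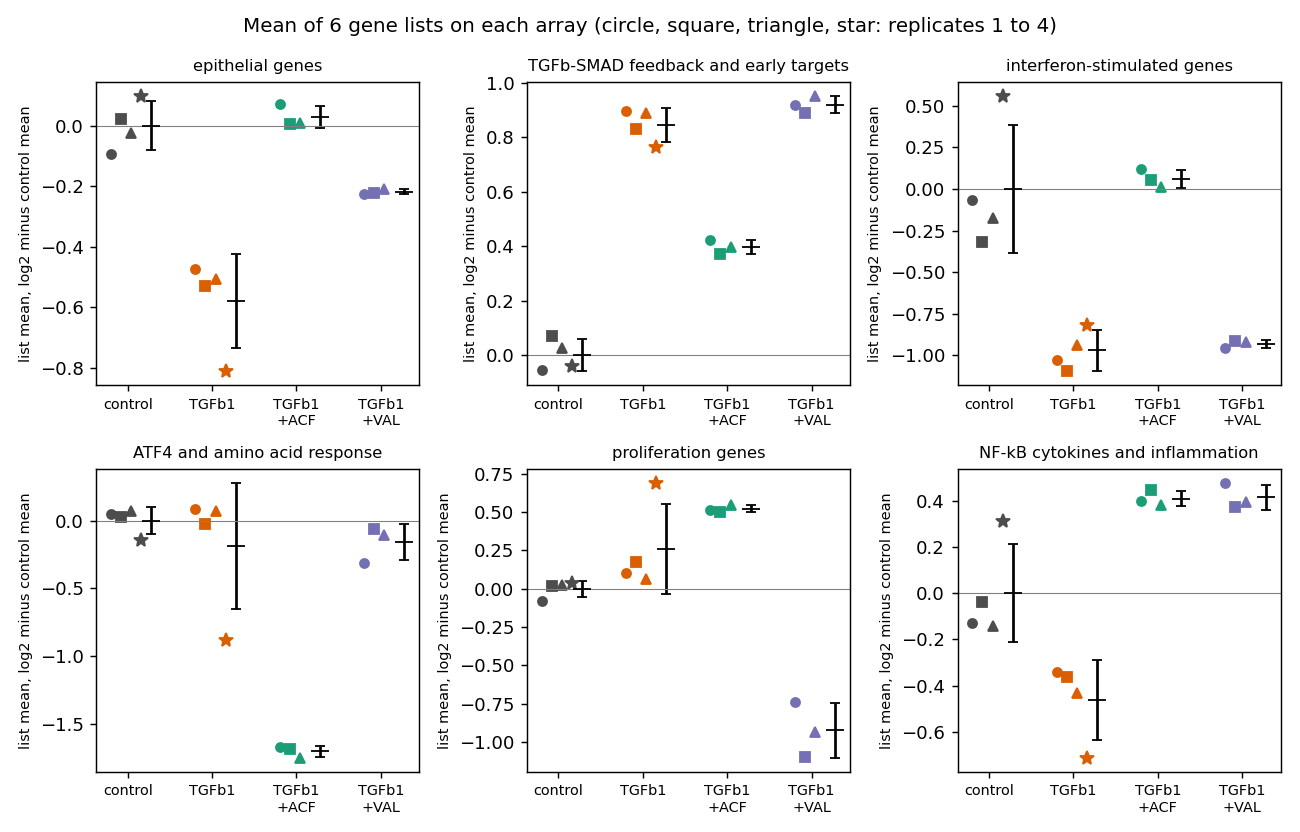
Mean log2 value of 6 gene lists in each array minus the mean of the control group, by group, with replicates 1 to 4 as circle, square, triangle and star and bars as mean ± SD (n = 4, 4, 3 and 3). The mean change of the ATF4 list was -1.51 with acriflavine against TGFb1, and TGFb1 replicate 4 differed from TGFb1 replicates 1 to 3 by -0.923 in it.

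Acriflavine with TGFb1 was compared with TGFb1 alone to ask what the dye changed in stimulated cells. CDH1 rose by 2.85 ± 0.28 (adjusted p = 3.49e-06) and COL1A1 fell by 3.88 ± 0.275 (adjusted p = 1.96e-07). Of the genes of amino acid synthesis and transport that the transcription factor ATF4 controls 26 of 33 fell, among them PHGDH (-3.76 ± 0.182), the first enzyme of serine synthesis, and ASNS (-3.06 ± 0.219), asparagine synthetase. 20 of 29 interferon-stimulated genes rose, with IFIT2 up by 2.88 ± 0.157. In all, 2660 genes rose and 2078 fell, and 408 and 345 of them changed at least 2-fold.

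The largest rise was in F3, tissue factor, the initiator of blood coagulation (4.18 ± 0.185, adjusted p = 6.48e-09). CXCL5 (3.67 ± 0.362), KRTAP2-3 (3.41 ± 0.292), ANXA3 (3.34 ± 0.236), IGFBP4 (3.22 ± 0.271), a binding protein of insulin-like growth factors, GLRX (3.07 ± 0.221), a glutaredoxin, and TST (3.02 ± 0.157), a mitochondrial sulfurtransferase, followed. The largest fall was in BCAT1, the cytosolic transaminase of branched-chain amino acids (-4.08 ± 0.261, adjusted p = 8.1e-08). It was followed by CTH (-3.90 ± 0.454), which makes cysteine from cystathionine, COL1A1, PHGDH, SLC7A11 (-3.75 ± 0.209), the cystine importer, ANK2 (-3.56 ± 0.262), DDIT4 (-3.50 ± 0.238), an inhibitor of mTORC1 signalling, and CCND2 (-3.39 ± 0.482), cyclin D2.

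26 of 33 measured genes of the ATF4 list fell, 1 rose and 6 did not pass (adjusted p = 1.56e-11 by camera, adjusted p = 0.316 with an estimated correlation; adjusted over the list alone, 1 rose and 28 fell). ATF4 itself fell (-1.04 ± 0.111), as did TRIB3 (-2.27), a stress-induced pseudokinase, and SESN2 (-1.76), a sestrin of nutrient sensing. Aminoacyl-tRNA synthetases, which charge tRNAs, fell in 13 of 19 and rose in 3 (adjusted p = 0.000153 by camera, adjusted p = 0.309 with an estimated correlation; adjusted over the list alone, 3 rose and 13 fell), with EPRS1 at -1.69, AARS1 at -1.65 and GARS1 at -1.51. Among 30 chaperones and degradation factors of the endoplasmic reticulum (ER), 11 fell and 2 rose (adjusted p = 0.0322 by camera, adjusted p = 0.517 with an estimated correlation; adjusted over the list alone, 2 rose and 11 fell), with XBP1 at -1.34 and HERPUD1 at -1.52. This ER list lost its call without TGFb1 replicate 4 (adjusted p = 0.121), without acriflavine replicate 2 (0.0533) and with the replicates 4 left out (0.116). HIF targets, the genes of the response to low oxygen, showed 6 raised, 11 lowered and 12 not passed of 29, with no shift of the list (adjusted p = 0.0865). VEGFA (-1.04) and ANGPTL4 (-2.66) fell, while HIF1A was at 0.00 (adjusted p = 0.991). Of 17 NRF2 targets 8 fell and 3 rose without a shift of the list (adjusted p = 0.0587), with HMOX1, heme oxygenase, at -2.85.

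Of 34 epithelial genes 16 rose, 3 fell and 15 did not pass (adjusted p = 0.00313 by camera, adjusted p = 0.358 with an estimated correlation; adjusted over the list alone, 16 rose and 3 fell). SPINT1, a protease inhibitor of epithelia, rose by 2.78, LSR, a protein of tricellular junctions, by 2.26 and EPCAM by 1.97. TGFb-SMAD genes fell in 14 of 24 and rose in 1 (adjusted p = 0.000192 by camera, adjusted p = 0.0514 with an estimated correlation; adjusted over the list alone, 1 rose and 14 fell). The receptor TGFBR1 was at -1.53, the co-repressor SKI at -1.92, SMAD7 at -0.70 and SNAI1 at -1.56 ± 0.158. Of 22 collagens and basement membrane genes 9 fell and 3 rose (adjusted p = 0.0116 by camera, adjusted p = 0.137 with an estimated correlation; adjusted over the list alone, 3 rose and 9 fell), with COL3A1 at -2.22. The mesenchymal list was split, with 4 raised and 9 lowered of 31 and no shift (adjusted p = 0.189; adjusted over the list alone, 4 rose and 9 fell). CDH2 (0.03, adjusted p = 0.768), VIM (-0.14, adjusted p = 0.0909) and FN1 (-0.27, adjusted p = 0.529, and 0.10 without TGFb1 4) did not pass. With the replicates 4 left out VIM passed at -0.14 (adjusted p = 0.0462).

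20 of 29 interferon-stimulated genes rose and 2 fell (adjusted p = 4.04e-05 by camera, adjusted p = 0.371 with an estimated correlation; adjusted over the list alone, 20 rose and 2 fell), with MX1 at 2.76 and IFIT1 at 2.24. NF-kB genes rose in 12 of 20 and fell in 1 (adjusted p = 0.00398 by camera, adjusted p = 0.358 with an estimated correlation; adjusted over the list alone, 13 rose and 1 fell), including the chemokines CXCL8 (2.27) and CCL20 (2.45). 19 of 35 nuclear genes of oxidative phosphorylation rose and none fell (adjusted p = 0.00266 by camera, adjusted p = 0.371 with an estimated correlation; adjusted over the list alone, 19 rose and 1 fell), for example NDUFA9 of complex I (0.83) and SDHA of complex II (0.65). Of 39 proliferation genes 12 rose and 1 fell (adjusted p = 0.0308 by camera, adjusted p = 0.671 with an estimated correlation; adjusted over the list alone, 12 rose and 1 fell), with E2F1 at 0.89. 4 of 8 metallothioneins, which bind metals, rose (adjusted p = 0.035 by camera, adjusted p = 0.531 with an estimated correlation; adjusted over the list alone, 4 rose and 0 fell), among them MT1F (1.66). The proliferation list lost its call without TGFb1 1 (adjusted p = 0.0648) or TGFb1 3 (0.0771), and the metallothioneins without TGFb1 4 (0.0676) or acriflavine 2 (0.0555). 11 of 21 genes of the histone deacetylase inhibitor list rose and 1 fell (adjusted p = 0.0252 by camera, adjusted p = 0.316 with an estimated correlation). Adjusted over the list alone, 11 rose and 1 fell. This rise started from a level below control, as the mean TGFb1 minus control difference of the list was -0.22 within replicates 1 to 3 and -0.517 within the replicates 4. The DNA damage and repair list did not pass with all arrays. It rose and passed without TGFb1 4 (mean 0.39, adjusted p = 0.00891 by camera), without the replicates 4 (0.0122) and with the block (0.34, 0.0276). Against replicates 1 to 3, TGFb1 replicate 4 differed by a mean of -0.998 in metallothioneins, -0.923 in ATF4 genes and -0.335 in NF-kB genes. The difference was -0.286 in the histone deacetylase inhibitor list, 0.205 in interferon genes, 0.579 in proliferation genes and 0.593 in DNA damage and repair genes.

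**Figure D3:**
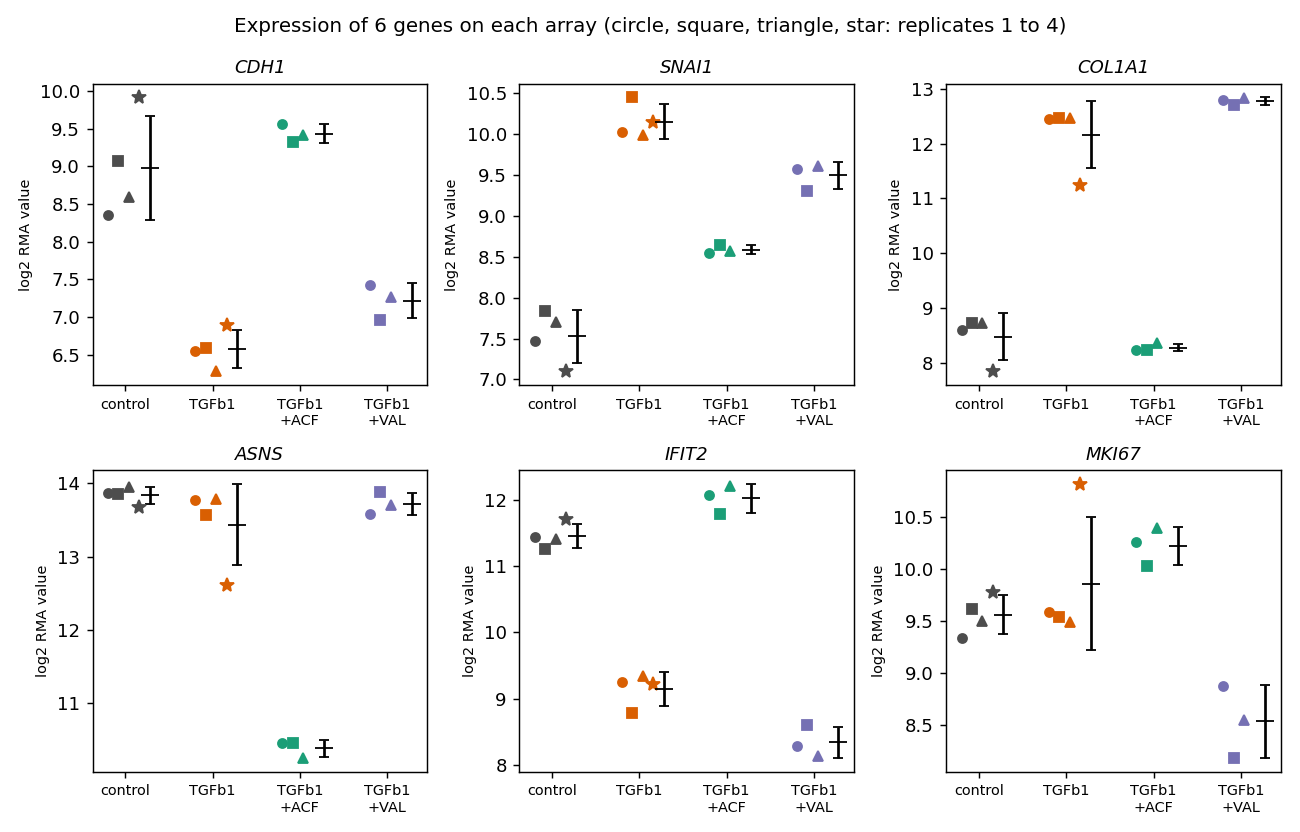
Log2 RMA intensity of CDH1, SNAI1, COL1A1, ASNS, IFIT2 and MKI67 in every array, by group, with replicates 1 to 4 as circle, square, triangle and star and bars as mean ± SD (n = 4, 4, 3 and 3). CDH1 changed by -2.40 with TGFb1 and from there by 2.85 with acriflavine, and ASNS by -3.06 with acriflavine.

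Valproate with TGFb1 was compared with TGFb1 alone as the second inhibitor. 37 of 39 proliferation genes fell, with CCNB2, cyclin B2, at -1.65 ± 0.091 (adjusted p = 9.98e-08) and MKI67 at -1.33 ± 0.272 (adjusted p = 0.00212). The chemokine CXCL8 rose by 2.98 ± 0.331 (adjusted p = 1.85e-05). CDH1 did not pass (0.63 ± 0.28, adjusted p = 0.104), while EPCAM rose by 0.67 and FN1 by 1.24. In all, 1643 genes rose and 1759 fell, and 268 and 177 of them changed at least 2-fold.

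The largest rises were in DNAJC12 (3.14 ± 0.198), a J-domain co-chaperone, CXCL8, TTC9B (2.86 ± 0.169), CCL20 (2.83 ± 0.208), C11orf96 (2.74 ± 0.248), MARCHF9 (2.69 ± 0.175), a ubiquitin ligase, LY96 (2.59 ± 0.262), the partner of the endotoxin receptor, and SERPINA3 (2.54 ± 0.195), a protease inhibitor. The largest falls were in RET (-1.96 ± 0.402), a receptor tyrosine kinase, KIF20A (-1.85 ± 0.406) and KIF2C (-1.75 ± 0.173), kinesins of mitosis, CDCA8 (-1.73 ± 0.134), a subunit of the chromosomal passenger complex, PIF1 (-1.72 ± 0.321), a DNA helicase, and OIP5 (-1.66 ± 0.174), which acts at centromeres.

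In the proliferation list 37 genes fell, none rose and 2 did not pass (adjusted p = 1.29e-23 by camera, adjusted p = 0.104 with an estimated correlation; adjusted over the list alone, 0 rose and 39 fell). TK1, thymidine kinase, was at -1.58 and TOP2A, topoisomerase II alpha, at -1.30. Of 21 genes of the DNA damage response and repair 14 fell and none rose (adjusted p = 3.23e-06 by camera, adjusted p = 0.275 with an estimated correlation; adjusted over the list alone, 0 rose and 15 fell), with BRCA1 at -1.18 and the helicase BLM at -1.11. Ribosome biogenesis genes fell in 18 of 31 and none rose (adjusted p = 3.95e-07 by camera, adjusted p = 0.0952 with an estimated correlation; adjusted over the list alone, 0 rose and 21 fell), among them POLR1A, the large subunit of RNA polymerase I, at -0.79. CDKN1A, the cell cycle inhibitor p21, rose by 1.02.

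Epithelial genes rose in 13 of 34 and none fell (adjusted p = 0.00322 by camera, adjusted p = 0.385 with an estimated correlation; adjusted over the list alone, 14 rose and 0 fell), with SPINT1 at 1.95 and keratin KRT7 at 1.37. SNAI1 fell by 0.66. The TGFb-SMAD list did not shift (adjusted p = 0.544), with 5 raised and 3 lowered of 24. Mesenchymal genes showed 9 raised and 5 lowered of 31 without a shift (adjusted p = 0.0589, and adjusted p = 0.0441 without TGFb1 3; adjusted over the list alone, 10 rose and 6 fell), with CDH2 at 0.64 and the protease inhibitor SERPINE2 at 1.60. Of 22 collagens and basement membrane genes 10 rose and 3 fell (adjusted p = 0.0511; adjusted over the list alone, 10 rose and 3 fell), and the list passed without TGFb1 3 (adjusted p = 0.0404), TGFb1 4 (0.0406) or valproate 1 (0.0393). 7 of 15 matrix proteases and inhibitors rose and none fell (adjusted p = 0.000775 by camera, adjusted p = 0.103 with an estimated correlation; adjusted over the list alone, 8 rose and 0 fell), with matrilysin MMP7 at 2.05 and PLAT, tissue plasminogen activator, at 1.19.

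NRF2 targets rose in 8 of 17 and none fell (adjusted p = 0.000252 by camera, adjusted p = 0.0721 with an estimated correlation; adjusted over the list alone, 9 rose and 0 fell), with ME1, malic enzyme, at 0.84 and SRXN1, sulfiredoxin, at 0.96. 8 of 14 neuronal and neuroendocrine genes rose and none fell (adjusted p = 0.000252 by camera, adjusted p = 0.0721 with an estimated correlation; adjusted over the list alone, 8 rose and 0 fell), with synaptotagmin SYT1 at 1.66 and chromogranin CHGB at 1.25. Lysosome genes rose in 10 of 26 (adjusted p = 0.000486 by camera, adjusted p = 0.25 with an estimated correlation; adjusted over the list alone, 10 rose and 0 fell) and genes of cholesterol synthesis in 6 of 19 (adjusted p = 0.00306 by camera, adjusted p = 0.562 with an estimated correlation; adjusted over the list alone, 8 rose and 0 fell), with LIPA, lysosomal acid lipase, at 0.74 and MSMO1, a sterol oxidase, at 0.82. NF-kB genes rose in 11 of 20 and fell in 1 (adjusted p = 0.000775 by camera, adjusted p = 0.275 with an estimated correlation; adjusted over the list alone, 11 rose and 1 fell). Of 21 genes that commonly respond to inhibitors of histone deacetylases 4 rose and 1 fell, and the list did not shift (adjusted p = 0.151). The interferon list (3 raised, 4 lowered of 29, adjusted p = 0.912) and the ATF4 list (2 raised, 1 lowered of 33, adjusted p = 0.954) did not shift. Without TGFb1 replicate 4 the mean change of the ATF4 list went from 0.03 to -0.20 and passed (adjusted p = 0.0303). With the replicates 4 left out CDH1 passed (0.74, adjusted p = 0.00214), and 5208 genes changed.

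The 280 genes that TGFb1 changed at least 2-fold were followed into the inhibitor groups to ask how much of the response remained. For the 136 raised genes the median TGFb1 change was 1.37. Their median change from TGFb1 was -0.71 ± 0.0281 with acriflavine (SD of 3 array medians) and 0.18 ± 0.0417 with valproate. The share of the TGFb1 change that remained was taken for each gene, and its median was 41.1% with acriflavine and 115% with valproate. For the 144 lowered genes the median TGFb1 change was -1.25. Their median change from TGFb1 was 1.13 ± 0.0602 with acriflavine and 0.41 ± 0.0328 with valproate, and the median share that remained was 16.5% and 71.5%. With all arrays and the 2-fold minimum each of these shifts was larger than the combined spread of both groups' arrays, which was between 0.0993 and 0.12.

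With acriflavine 97 of the 136 raised genes fell back, 10 rose further and 29 did not pass. COL1A1 and ANGPTL4 were among those that fell back, and so was ADAM19 (-2.50). Of the 144 lowered genes 101 rose back, 10 fell further and 33 did not pass, with CDH1, IFIT2, CXCL5 and MX1 among those that rose. With valproate 20 of the raised genes fell back and 40 rose further, and 62 of the lowered genes rose back and 9 fell further. As TGFb1 arrays stood on both sides, the genes were also chosen with 2 of the 4 TGFb1 arrays and compared with the other 2. The medians over 6 such splits were -0.64 and 0.87 for acriflavine and 0.26 and 0.32 for valproate, for raised and lowered genes. In the TGFb1 arrays that did not choose the genes, the median TGFb1 change was 1.31 and -1.14. The shares that remained were not recomputed in the splits, and those above rest on the arrays that chose the genes. The shift of the raised genes with valproate was 0.0451 without TGFb1 replicate 4, less than the spread with all arrays, and turned to -0.0281 over genes chosen without a minimum fold.

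**Figure D4:**
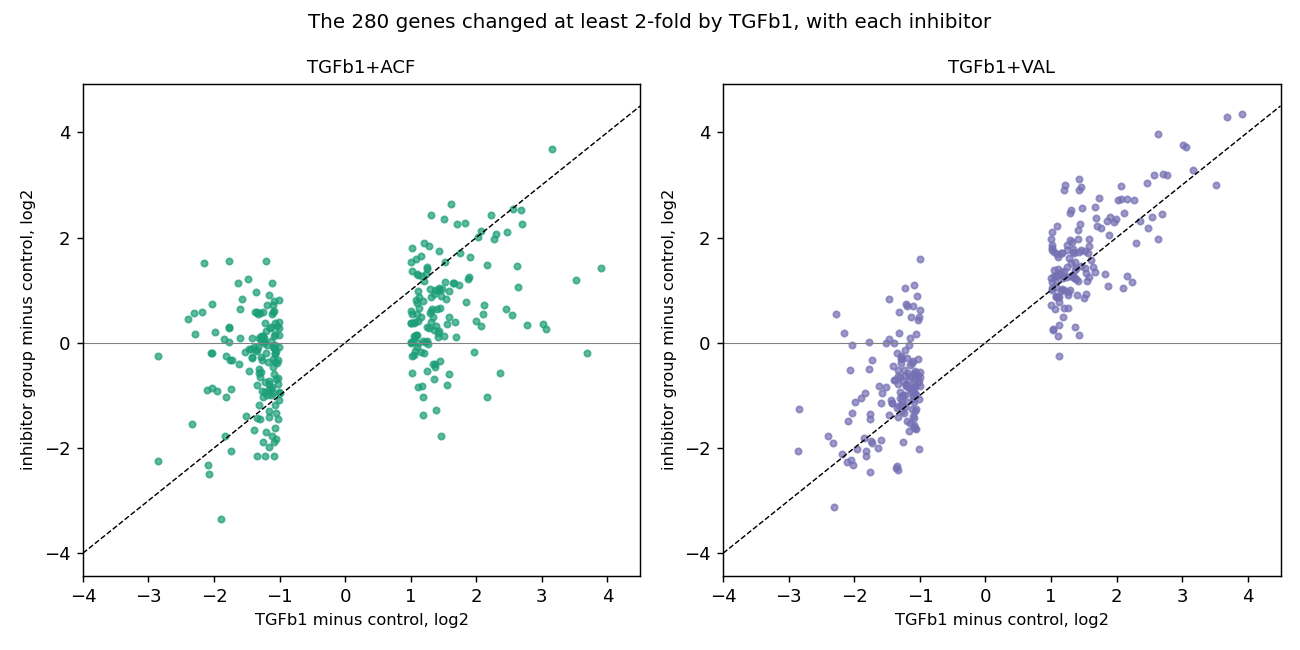
Log2 change of 280 genes in inhibitor plus TGFb1 minus control (vertical axis) against TGFb1 minus control (horizontal axis), for acriflavine and valproate, 1 point per gene, with a dashed line of equal change. The median of the 136 raised genes was 0.61 with acriflavine and 1.62 with valproate, and that of the 144 lowered genes was -0.24 and -0.87.

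Acriflavine with TGFb1 was compared with control to show what still differed from unstimulated cells. CDH1 was at 0.45 (adjusted p = 0.205) and COL1A1 at -0.20 (adjusted p = 0.584), neither past the test, while SNAI1 (1.06), COL4A1 (2.54) and ADAM19 (1.41) stayed above control. The genes farthest from control were F3 (4.24 ± 0.185), TUBA4A (3.69 ± 0.101) and IGFBP4 (3.07 ± 0.271) above and CTH (-4.55 ± 0.454), SLC7A11 (-4.30 ± 0.209) and BCAT1 (-4.25 ± 0.261) below. In all, 2839 genes were higher and 2354 lower than control.

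28 of 33 ATF4 genes were lower than control and 1 was higher (adjusted p = 2.41e-12 by camera, adjusted p = 0.341 with an estimated correlation; adjusted over the list alone, 1 rose and 28 fell), with ASNS at -3.46 and TRIB3 at -2.75. Proliferation genes were higher in 23 of 39 and lower in none (adjusted p = 0.000115 by camera, adjusted p = 0.69 with an estimated correlation; adjusted over the list alone, 25 rose and 0 fell), with CDC6, a factor of replication licensing, at 1.32 and E2F1 at 1.30. Epithelial genes were higher in 8 and lower in 8 of 34 without a shift (adjusted p = 0.656), with LSR at 1.63. TGFb-SMAD genes were higher in 12 and lower in 3 of 24 (adjusted p = 0.068), NOG at 2.10 and TGFBR1 at -1.49. Interferon genes were higher in 6 and lower in 5 of 29 (adjusted p = 0.912), with IRF7 at -1.27. Without control replicate 4, CDH1 passed at 0.76 (adjusted p = 0.00481), and without control replicate 1 its value was 0.24. With the replicates 4 left out COL1A1 passed at -0.41 (adjusted p = 0.000147), and so did the TGFb-SMAD list at a mean of 0.38 (0.0216). The mesenchymal list did not pass with all arrays. It passed above control without the replicates 4 (mean 0.42, adjusted p = 0.019 by camera) and with the block (0.41, 0.0176). It also passed without control 4 (0.0203), acriflavine 1 (0.0457) or acriflavine 2 (0.0375). The DNA damage and repair list likewise passed above control only in other fits, such as that without the replicates 4 (0.39, 0.019).

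Valproate with TGFb1 was compared with control in the same way. CDH1 stayed below control (-1.77, adjusted p = 0.000247), as did ELF3 (-2.02) and EPCAM (-0.71), and SNAI1 (1.97), FN1 (2.00) and CDH2 (1.11) were above it. The largest differences were in ADAM19 (4.35 ± 0.228), COL1A1 (4.30 ± 0.275) and NEDD9 (3.98 ± 0.15), a scaffold of focal adhesions, above control and in IFIT2 (-3.11 ± 0.157), RGCC (-2.46 ± 0.17) and GRHL3 (-2.43 ± 0.122), an epithelial transcription factor, below it. In all, 1841 genes were higher and 2150 lower than control.

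Proliferation genes were lower than control in 36 of 39 (adjusted p = 1.04e-14 by camera, adjusted p = 0.149 with an estimated correlation; adjusted over the list alone, 0 rose and 38 fell), with TK1 at -1.34. TGFb-SMAD genes were higher in 17 of 24 (adjusted p = 7.3e-09, and adjusted p = 0.00229 with an estimated correlation; adjusted over the list alone, 18 rose and 0 fell) and mesenchymal genes in 15 of 31 (adjusted p = 3.17e-07, and adjusted p = 0.00229 with an estimated correlation; adjusted over the list alone, 16 rose and 1 fell). Collagens and basement membrane genes were higher in 10 of 22 and lower in 2 (adjusted p = 0.00155, and adjusted p = 0.0424 with an estimated correlation; adjusted over the list alone, 11 rose and 2 fell). Interferon genes were lower in 20 of 29 (adjusted p = 3.17e-07 by camera, adjusted p = 0.279 with an estimated correlation; adjusted over the list alone, 1 rose and 21 fell), with IFIT3 at -2.35. Genes of cholesterol synthesis were higher in 13 of 19 and lower in none (adjusted p = 7.39e-06 by camera, adjusted p = 0.279 with an estimated correlation). Adjusted over the list alone, 16 rose and 0 fell, and HMGCS1, an early enzyme of the pathway, was at 1.20. Part of this difference was present with TGFb1 alone. The mean TGFb1 minus control difference of the list was 0.289 within replicates 1 to 3 and 0.308 within the replicates 4.

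The inhibitors were compared directly on the same TGFb1 background, each at its own dose. CDH1 was higher with acriflavine than with valproate by 2.22 ± 0.299 (adjusted p = 3.4e-05), COL1A1 was at -4.50 ± 0.294 and FN1 at -1.51. The largest differences were F3 (4.07 ± 0.198), H2BC11 (3.99 ± 0.133), a histone H2B, IFIT2 (3.68 ± 0.168) and TNNC1 (3.34 ± 0.436) above and CCND2 (-5.05 ± 0.515), BCAT1 (-4.88 ± 0.279), DNAJC12 (-4.88 ± 0.212), SLITRK6 (-4.73 ± 0.19) and ANK2 (-4.73 ± 0.281) below. In all, 3074 genes were higher and 2530 lower with acriflavine.

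Of 39 proliferation genes 38 were higher with acriflavine and none lower (adjusted p = 2.89e-15 by camera, adjusted p = 0.172 with an estimated correlation; adjusted over the list alone, 38 rose and 0 fell), with FOXM1 at 2.07 and the mitotic kinase AURKA at 2.03. ATF4 genes were lower with acriflavine in 24 of 33 (adjusted p = 2.44e-09 by camera, adjusted p = 0.317 with an estimated correlation; adjusted over the list alone, 2 rose and 25 fell). Interferon genes were higher in 18 of 29 (adjusted p = 0.000639 by camera, adjusted p = 0.439 with an estimated correlation; adjusted over the list alone, 18 rose and 4 fell), with IFIT3 at 2.93. Lower with acriflavine were TGFb-SMAD genes in 14 of 24 (adjusted p = 0.000373, and adjusted p = 0.0348 with an estimated correlation; adjusted over the list alone, 3 rose and 15 fell) and collagens in 14 of 22 (adjusted p = 0.000373, and adjusted p = 0.0348 with an estimated correlation; adjusted over the list alone, 2 rose and 14 fell). NRF2 targets (adjusted p = 0.000971) and neuronal genes (adjusted p = 0.000486) were lower as lists too, each with adjusted p = 0.0498 with an estimated correlation, with HMOX1 at -3.05 and SYT1 at -3.84. The epithelial list did not pass (13 higher, 8 lower of 34, adjusted p = 0.38).

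Against TGFb1 alone, 591 genes rose with both inhibitors and 380 fell with both, 449 rose with acriflavine and fell with valproate, and 354 did the opposite. Independent lists of the same sizes would share 402 and 336 genes in the same direction and 430 and 314 in opposite ones. CCL20, CXCL5, MMP7 and GLRX rose with both, and SNAI1 fell with both. Both comparisons share the TGFb1 arrays. Pearson's r between both sets of changes across genes, which are not independent replicates, was 0.058. It was 0.426 in simulated groups without change, where only the shared arrays link both sets. Real changes add to the spread by which r is divided, so these values of r cannot be set against each other. The covariance, which is not divided by the spread, was 0.0142, against 0.0104 (0.00954 to 0.0113) in the simulated groups. When each inhibitor was compared with different TGFb1 arrays, r was -0.032 and the covariance was -0.00856 (-0.0274 to 0.0148 over the splits). The sign of the covariance thus depended on the arrays used. With different TGFb1 arrays the counts were 710 in the same and 722.5 in opposite directions (medians of 6 splits), against 971 and 803 with shared ones. Independent lists of the sizes in these splits would share 320 raised and 265 lowered genes (medians), and for opposite directions this was not computed. Without TGFb1 replicate 4 the counts were 1490 and 1051.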

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

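The tests of explanations in this part were chosen only after the results they concern were seen. For each gene named in the text and each tested list, the 4 control and the 4 TGFb1 arrays were searched for a single array far from the others, by its gap to the nearest array as a share of the group's range. Chance gives such an array in about 1 in 20 groups, and 49 of 302 were found here, 29 of them TGFb1 replicate 4 and 15 control replicate 4.

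TGFb1 replicate 4 was the lowest array in the means of the epithelial list (a share of 0.8292), the ATF4 list (0.887), the aminoacyl-tRNA synthetases (0.845), the histone deacetylase inhibitor list (0.955) and the metallothioneins (0.836), and the highest in the ER chaperones (0.973), the DNA damage and repair list (0.931) and the heat shock list (0.860). It was the lowest in the ATF4-related genes AARS1 (a share of 0.893), DDIT4 (0.899), PHGDH (0.857), SESN2 (0.873) and TRIB3 (0.949). It was also the lowest in COL1A1 (0.983), H3C4 (0.894), HERPUD1 (0.926), HMOX1 (0.911), IGFBP4 (0.844), IRF7 (0.922), KRTAP2-3 (0.917), MARCHF9 (0.8695), NOG (0.849), SPINT1 (0.880), TNNC1 (0.9145) and XBP1 (0.968). It was the highest in IFIT1 (0.900) and in the cell cycle and DNA genes MKI67 (0.923), PIF1 (0.852) and TOP2A (0.874).

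Control replicate 4 was the lowest array in ATF4 (a share of 0.973), COL1A1 (0.857), DDIT4 (0.9755), E2F1 (0.941), IGFBP4 (0.8905), ITGA5 (0.864), MT1F (0.835), RBP4 (0.8955), TGFB1 (0.963) and TNNC1 (0.883). It was the highest in CCL20 (0.83), HLA-F (0.949), IFIT1 (0.930), MMP7 (0.937) and SLITRK6 (0.8495). Control replicate 1 was the lowest in the mean of the proliferation list (0.849). Control replicate 2 was the lowest in the heat shock list (0.9515), HERPUD1 (0.882) and LCN2 (0.8905), and TGFb1 replicate 3 in GRHL3 (0.946).

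The first pattern is that replicate 4 of control and of TGFb1 stood apart from replicates 1 to 3. Their deviations correlated across genes at r = 0.705, where genes are not independent replicates, so a difference shared by both, such as a separate run, is a candidate explanation. Whether TGFb1 replicate 4 held acriflavine-treated RNA was tested by its share of the acriflavine change in the 100 most raised and 100 most lowered genes, which was 0.123 ± 0.0335 and 0.275 ± 0.0353 (control replicate 4: 0.132 and 0.034), with a difference of 0.152 ± 0.0487. It decided nothing, as 0.123 lay within its spread of the bound of 0.1 and only the most extreme genes were used. A second test, added only after that result, gave the admixture needed on the linear scale. It was 0.147 ± 0.0162 for 463 raised and 0.340 ± 0.0341 for 368 lowered genes (control replicate 4: 0.104 and 0.0571). A single admixture would not give this difference of 0.194, while on the log2 scale the same genes gave 0.227 and 0.229. In both tests ± is a standard error from resampling genes, which are not independent replicates. It does not measure the spread between arrays, as TGFb1 replicate 4 is 1 array. With that limit the second test argues only weakly against such RNA as the whole cause. An admixture on top of a batch stays open, and no biological explanation was tested, because the labels name no difference for these samples.

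The second pattern is that ATF4 genes were lower with acriflavine than with TGFb1 alone, with a mean change of -1.51. A general loss of short-lived transcripts would lower the immediate early genes too, unless they were also induced. Their mean change was 0.12, with a combined SD of 0.159, and transcript stability was not measured. The choice of 1 probe set per gene is argued against by a mean of -1.46 with all probe sets of a gene, and the replicates 4 by a mean of -1.74 without them. A lower activity of ATF4, whose own transcript fell by 1.04, may underlie the pattern as a hypothesis, but its protein was not measured. Whether the change needs TGFb1 stays open, because acriflavine alone was not analysed here.

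The third pattern is that interferon-stimulated genes were lower with TGFb1 and higher again with acriflavine. The replicates 4 as the whole cause are argued against by a mean of -0.834 for TGFb1 against control without them. The growth state of the cells was weighed with valproate, which lowered the proliferation genes and left the interferon list at 0.0394 from TGFb1, with a combined SD of 0.124. That argues against the growth state only if valproate has no opposing effect on these genes, which was not tested. A response of interferon genes to the nucleic acid binding dye itself, or a reversal of the TGFb1 effect, may each underlie the rise with acriflavine, and without an acriflavine group that lacks TGFb1 neither was tested.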

How the results depend on the processing

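All settings were chosen before the results were seen except the batch term for the replicates 4 and leaving out TGFb1 replicate 2 with them. A reversal was counted only where the value passed in the main or the changed setting. Values that passed in neither count as kept, whatever their direction. Among values of single named genes under all settings other than leaving out 1 array, 11457 were kept in this sense, 400 no longer passed, 695 newly passed and 7 reversed, and with 1 array left out these counts were 5639, 226, 116 and 1. Of list results 2280 were kept in the same sense, 109 no longer passed, 189 newly passed and 2 reversed, and with 1 array left out 1235, 27, 39 and 1. Counts of changed genes and of shifted lists are given for TGFb1 against control, acriflavine against TGFb1, valproate against TGFb1, acriflavine against control, valproate against control and acriflavine against valproate, in this order, where all 6 are named. With every probe set separately, where more features are tested, 4592, 11824, 8195, 13147, 9960 and 14005 changed, 24 lists shifted for acriflavine and 18 for valproate against TGFb1, 17 and 21 against control, and the inhibitors shared 2281 in the same and 1811 in opposite directions. A minimum of 2-fold left 280, 753, 445, 792, 638 and 1288 genes and an overlap of 60 and 29. At an adjusted p of 0.01, 1051 genes changed with TGFb1 and 2199 with valproate against TGFb1. Fits of 2 groups alone gave fewer genes in the 3 comparisons that use the TGFb1 group (963, 3708 and 2263), more in the others (5981, 4690 and 7372) and an overlap of 551 and 482. With the replicate block 3148 genes changed with TGFb1 and 1552 were shared in the same direction. Without the replicates 4, 3155 genes changed with TGFb1 and 5208 with valproate against TGFb1, and the overlap was 1956 and 1336. With a batch term for them 3547 genes changed with TGFb1 and the overlap was 1715 and 1262. With TGFb1 replicate 2 also left out, 5364 genes changed with valproate against TGFb1 and 6292 against control, and the overlap was 2212 and 1420. The TGFB1 gene in acriflavine against TGFb1, at 0.06 and not past the test, reversed to -0.28 with the block and with the batch term, to -0.29 without the replicates 4 and to -0.20 without TGFb1 replicate 2 as well. In valproate against TGFb1, TRIB3 reversed from 0.07 to -0.41 without the replicates 4 and to -0.39 without TGFb1 replicate 2 as well, the mean of the ATF4 list reversed from 0.03 to -0.20 and -0.24, and NDUFB3 reversed to -0.0926 with the mean of probe sets. No filter on dim genes gave 14 lists for acriflavine against control. With an estimated correlation 2, 0, 0, 0, 4 and 4 lists shifted, and by fry 24 did for acriflavine against TGFb1 and 16 for acriflavine against control. The shift of the genes that TGFb1 raised was -0.919 with acriflavine when the dimmest 60% were left out. Without a minimum fold the shifts were -0.179 and 0.285 with acriflavine and -0.0281, a reversal, and 0.208 with valproate, for raised and lowered genes. They were -0.879 and 1.32 with acriflavine, and 0.0736 for raised genes with valproate, without the replicates 4 and TGFb1 replicate 2, and 0.871 for lowered genes with acriflavine when TGFb1 arrays were split 2 and 2. Apart from more features tested and stricter limits, the cause was not tested. With 1 array left out the counts of changed genes ran from 1387 to 3149, 3748 to 5614, 2588 to 4397, 4237 to 5044, 3064 to 3990 and 4725 to 4948, and those of lists from 12 to 19, 11 to 15, 10 to 14, 6 to 8, 13 to 15 and 16 to 18. The overlap ran from 699 to 1490 and from 600 to 1051, and the shifts from -0.808 to -0.697 and 1.02 to 1.21 with acriflavine and 0.0451 to 0.222 and 0.386 to 0.505 with valproate. For valproate against TGFb1, TRIB3 ran from -0.41 to 0.24 and the mean of the ATF4 list from -0.20 to 0.12. Among these counts of genes and lists and overlaps, moves by over 1.5 times came from leaving out TGFb1 replicate 4. That gave 3149 genes for TGFb1 against control and 1490 shared in the same direction. A shift counted as moved where it changed by at least the combined spread of both groups' arrays. This too came from leaving out TGFb1 replicate 4, with the shift of 0.0451. Leaving it out also gave the -0.41 of TRIB3 and the -0.20 of the ATF4 list, while the tops of these 2 ranges came without other TGFb1 replicates. A planned test of RNA quality, and its repeats without each array, was not run. Dim genes limit the reach, as the reported comparisons leave out genes with a mean under 6.88.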

Other observations

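The gene families and the tests in this part were chosen after the data were seen, except the comparison with other splits of the arrays, and other families, such as the collagens, were looked at too. Histone genes, whose nearly identical copies probe sets cannot always tell apart, rose with acriflavine against TGFb1 in 13 of 22 and fell in 3 (adjusted p = 0.000652 by camera, and adjusted p = 0.134 with an estimated correlation). With valproate none rose and 12 fell (adjusted p = 8.35e-05, and adjusted p = 0.0519 with an estimated correlation), and between the inhibitors 18 were higher with acriflavine and 1 lower (adjusted p = 8.33e-07, and adjusted p = 0.0445 with an estimated correlation). H2BC11 was at 2.69 with acriflavine and at -1.30 with valproate, H3C4 at 1.08 and -1.11 and the linker histone H1-2 at 1.52 and -0.82. H2AC20 fell with both (-1.79 and -1.41).

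Mitochondrial ribosomal protein genes, which serve translation inside mitochondria, rose with acriflavine in 51 of 74 and fell in 5 (adjusted p = 1.78e-08, and adjusted p = 0.134 with an estimated correlation). Genes of proteasome subunits, regulators and assembly factors rose in 25 of 42 and fell in 3 (adjusted p = 0.000175, and adjusted p = 0.134 with an estimated correlation). HLA genes, which present antigens, rose with acriflavine in 4 of 9 (adjusted p = 0.028, and adjusted p = 0.134 with an estimated correlation) and with valproate in 6 of 9 (adjusted p = 0.00132, and adjusted p = 0.0519 with an estimated correlation), and none fell. HLA-F rose by 1.92 with acriflavine and 2.13 with valproate, and HLA-B by 1.16 and 0.72.

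Other splits of the same arrays into groups of the same sizes were tested for the number of genes that changed. In each of the 5 comparisons with 35 splits, 1 split, the real one, gave as many genes, a share under 1 in 20. In 4 of them the replicate numbers did not pair the arrays by the rule, and replicate 4, which stood apart, was on 1 side only. The arrays were thus not interchangeable, and the splits do not exclude chance as the source of these counts. The real and the highest other counts were 1997 and 1128 for TGFb1 against control, 4738 and 3666 for acriflavine against TGFb1, 3402 and 2469 for valproate against TGFb1, 5193 and 2195 for acriflavine against control and 3991 and 1879 for valproate against control. For both comparisons of an inhibitor with TGFb1 the highest other split put TGFb1 replicates 1 to 3 on one side and TGFb1 replicate 4 with the inhibitor arrays on the other, and without the replicates 4 the counts were 6291 and 5208. For TGFb1 against control, where the replicate numbers met the rule for pairs, the 8 splits that part all 4 pairs are too few for a share under 1 in 20, with 1997 genes in the real one and 0 as the highest other. The remaining splits put both arrays of a same-numbered pair on one side. For acriflavine against valproate the 10 splits are too few, with 5604 genes in the real split and 0 as the highest other.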
